A study of Mus musculus with 4 samples.

How the data were processed

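Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the genomic sites bound by NR6A1, an orphan nuclear receptor also known as germ cell nuclear factor. The labels describe 4 libraries from monoclonal immortalized mouse mesenchymal stem cells that carry floxed Dicer alleles and are called Dicer wild type. In 2 of them the cells carried a retrovirus for NR6A1 with Flag and HA tags, and in 2 they carried the vector. Per the labels' protocols, stably selected cells were fixed with formaldehyde for 10 min, nuclei were sonicated, and fragments were recovered with an antibody to HA bound to magnetic beads, at 5 µg of antibody. The same HA antibody is given for the vector libraries, which lack the tagged protein by the labels' description.

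The values used were 2 peak lists, 1 for each NR6A1 replicate, so peaks were called per sample and not on pooled samples. Values for the vector libraries were not analysed here. Bowtie 0.12.7, MACS and the mouse genome build mm9 are named in the submitters' processing notes, without their roles, and the version of MACS is not given in the sources used here. Which library served as the control in peak calling and the peak threshold are likewise not given in the sources used here. Each deposited peak has a chromosome, a start, an end, a MACS peak number and a score. The deposited score was taken as MACS's log-transformed p-value of the peak, with higher scores for smaller p-values, from its range and 2 decimals. It starts just above 200 in both lists, which fits a common minimum score. Exactly 3100 is shared by 239 peaks of replicate 1 and 187 of replicate 2. Above it lie 26 and 24 peaks, with scores up to 3218.29 and 3219.64. For these tied values 3100 is called the ceiling here, although it is not the highest score. How peaks at exactly 3100 compare in strength with those above it is unknown from the lists. The order of peaks at or above 3100 is therefore not read as an order of strength. A score depends on the depth and the background of its own library. It is the authors' value for that peak, and was used to rank or filter peaks within a list and to set the scores of partner peaks side by side. Such ratios of scores between the lists include any difference in depth or background between the libraries. Read depth is unknown from these lists. No read counts per peak were used here, so no fold enrichment or test of binding strength between libraries is given.

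Positions are those of the deposited lists on mm9, written with the first base as 1. Chromosome lengths of mm9 were taken from GenomeInfoDb 1.38.1 in R 4.3.3. The gene table at hand is of another build, GRCm38, and coordinates were not moved between builds. The assignment of peaks to promoters and genes, the tests of gene lists fixed before the data were examined, the search for the NR6A1 motif and the description of the Nr6a1 locus, where reads of the transgene would align, were therefore not run. The rule for named items, fixed before the data were examined, provided for this case and names the 10 shared peaks with the best mean rank of the score over both replicates, by position. It was applied to the scores as deposited, so scores above 3100 ranked ahead of 3100 in that selection. Other regions in the text were chosen after their values were seen, as the windows, clusters or runs with the most peaks.

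Peaks of the 2 lists were partners when they overlapped by at least 1 bp (bedtools 2.31.1, with the same counts from Python 3.11.15, numpy 2.4.6 and pandas 2.3.3). Overlapping peaks of both lists were merged into regions. The number of partners was compared with 1000 shuffles in which every replicate 2 peak was placed at random on its own chromosome with its own width, which allows a smallest p of 0.001. Shuffles can also land in unsequenced or unmappable stretches, so shuffles within 50 to 100 kb of each peak were added after seeing the data. Rank correlations (scipy 1.17.1) are across peaks or across windows of 1 library pair. Peaks are not independent replicates, and no p-value is attached to those. Shares carry 95% Wilson intervals, which cover counting error only. Clustering was measured as the share of peaks with another midpoint of the same list within 10 kb, against 1000 shuffles. Peak density was counted per chromosome and in windows of 1 Mb. The choices of these last measures, and of a score of 1000 or 3000 as a limit for strong peaks, were made after the lists had been seen.

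The overlap and shuffle code was tested on simulated lists made with the sizes and widths of the real ones, except that common sites had the replicate 1 width in both lists. Sites were placed at random, so the clustering of the real lists was not simulated. Peaks overlapping within a list were then removed. Of 21405 simulated replicate 1 peaks, 8946 had a common site placed in the other list and 9027 were found overlapping, the surplus being chance overlaps. With no common site, 163 of 21401 overlapped, against 164.9 in shuffles. Alternatives fixed before the data were examined were a 50% reciprocal overlap, midpoints within 100 bp, the upper 50% of each list by score, equal list sizes, and lists without the widest 1% of peaks and without unplaced contigs. The 50% reciprocal overlap was set against 100 shuffles only, which allows a smallest p of 0.01. Alternatives added later were 2 other kinds of shuffle, removal of peaks at or above 3100, autosomes only, and neighbour distances of 5 and 50 kb. With 1 list per replicate and 2 replicates, nothing in the labels says whether the replicates came from separate infections or cultures, so agreement between the lists may be technical in part.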

Results

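The series asked which genomic sites NR6A1 occupies directly when it is expressed in adult mesenchymal stem cells. NR6A1 is a nuclear receptor whose gene is, per the series title, repressed by the microRNA let-7. Peaks of tagged NR6A1 were given for 2 replicates (n = 2), and values for the 2 vector libraries were not analysed here, so the background of the HA antibody is not set beside the values below. Replicate 1 had 21507 peaks and replicate 2 had 16160. They covered 12.74 Mb and 10.9 Mb. The median peak was 538 bp wide in replicate 1 (quartiles 462 and 665) and 613 bp in replicate 2 (quartiles 530 and 742). The authors' peak score had a median of 417 in replicate 1 and 394 in replicate 2. Read depth is unknown, and the difference in peak number has no replicate check, since there is 1 list for each replicate.

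The first comparison was between the replicates, which gives the sites found in both. NR6A1 peaks of the replicates fell on the same 9009 regions, which is 31.7% of the 28444 regions in either list, while 12317 regions were in replicate 1 only and 7118 in replicate 2 only. Of the replicate 1 peaks, 9190 or 42.7% overlapped a replicate 2 peak (95% Wilson interval 42.1 to 43.4%). Of the replicate 2 peaks, 9042 or 56.0% overlapped a replicate 1 peak (55.2 to 56.7%). When the replicate 2 peaks were placed at random on their chromosomes, 183 ± 13.6 replicate 1 peaks (SD over 1000 shuffles) overlapped one, so the observed number was 50.3-fold higher (one-sided permutation p = 0.001, the smallest that 1000 shuffles allow). Moving each peak by only 50 to 100 kb, which keeps the density of its neighbourhood, gave 387 ± 19.3 overlaps (SD over 1000 shuffles), and the observed number was 23.8-fold higher. The midpoints of partner peaks lay a median of 37.0 bp apart (quartiles 16.5 and 75.5), and 81.6% of partners lay within 100 bp. The replicate 2 peak was the wider partner in 70.8% of 9190 pairs, with a median width ratio of 1.14.

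Peaks with a high score had a partner more often in both replicates. In replicate 1 the share with a partner was 26.4% in the lowest decile of scores (24.5 to 28.3%) and 65.2% in the highest (63.2 to 67.2%). In replicate 2 it was 34.0% in the lowest decile (31.8 to 36.4%) and 90.0% in the highest (88.5 to 91.4%). Peaks with a partner had a median score of 521 in replicate 1, against 363 for those without. The medians in replicate 2 were 510 and 314. The replicates differed at the top of their lists. Of 3424 replicate 1 peaks with a score of 1000 or more, 1293 or 37.8% had no partner (36.2 to 39.4%), whereas 280 of 2264 such replicate 2 peaks or 12.4% had none (11.1 to 13.8%). At a score of 3000 or more, 75 of 280 replicate 1 peaks had no partner, or 26.8% (21.9 to 32.3%), and 9 of 227 in replicate 2, or 3.96% (2.10 to 7.36%). These intervals cover counting error over peaks and not the spread between cultures. The shares for the highest decile move with the definition of a partner: with midpoints within 100 bp, 50.3% of replicate 1 and 30.7% of replicate 2 had none, so the gap between the replicates remained and its ratio shrank.

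**Figure D1:**
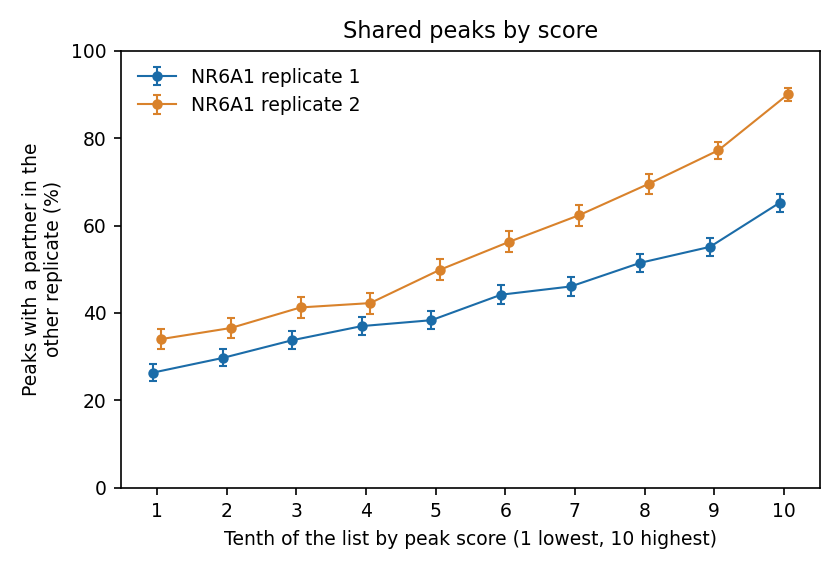
Percentage of peaks that overlap a peak of the other replicate (y axis) by decile of the list ranked on the authors' peak score (x axis), for NR6A1 replicates 1 and 2, with 95% Wilson intervals as bars. The share rises from 26.4% to 65.2% in replicate 1 and from 34.0% to 90.0% in replicate 2.

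Partner peaks ranked only partly alike. Over 9190 partner pairs the scores had a Spearman rho of 0.38 across peaks (bootstrap 95% interval 0.36 to 0.40), which is not a correlation across samples. Their log2 ratio had an SD of 1.11, and 65.5% of pairs had scores within 2-fold of each other, with no correction for the depth or background of each library. In 998 pairs both scores were at 1000 or more, and in 53 pairs both were at 3100 or more, the value treated here as the ceiling.

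**Figure D2:**
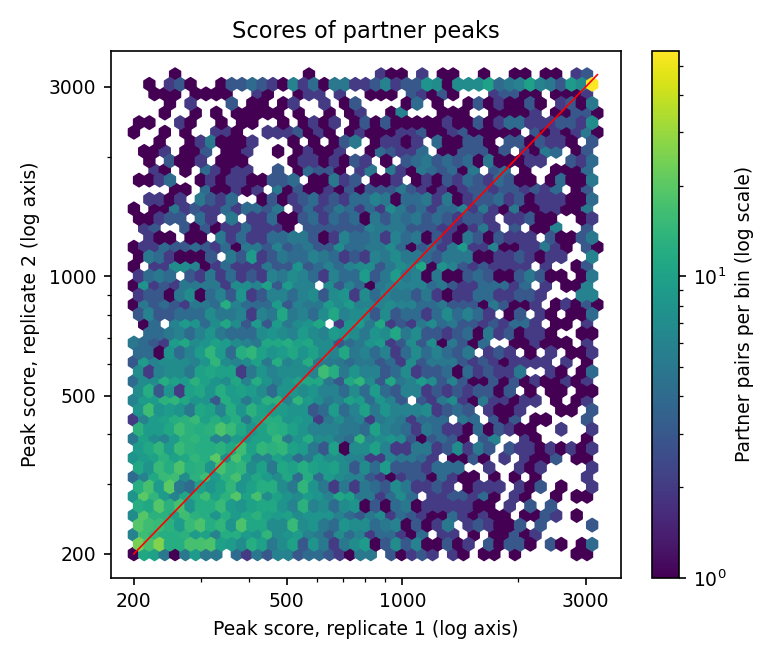
Authors' peak score in replicate 2 (y axis, log) against replicate 1 (x axis, log) for the 9190 partner pairs, as hexagonal bins coloured by the number of pairs on a log scale, with the line of equality in red. The pairs spread widely about the line (rho 0.38), and the bright bin at the upper right holds pairs at the ceiling of 3100.

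The shared peaks with the best mean rank of the scores as deposited were on autosomes. The first was on chromosome 15 at 79782265 to 79783326 in replicate 1, with a score of 3184.15, and at 79782221 to 79783447 in replicate 2, with a score of 3100. Chromosome 18 held 3 of the first 8. Their replicate 1 positions were 33537432 to 33538329, 60765594 to 60766412 and 79663389 to 79664537, and their replicate 2 scores were 3100, 3187.32 and 3145.96. Chromosome 3 held 2 of the first 8, at 137215269 to 137216463 and at 62941267 to 62942250 in replicate 1, with replicate 2 scores of 3100 and 2947.5. The others were on chromosome 10 at 33904727 to 33905964 and on chromosome 7 at 89682377 to 89683147, with replicate 2 scores of 3202.17 and 3194.93. Ranks 9 and 10 could not be given, because 46 pairs tied there with a score of 3100 in both replicates. Among those were pairs on chromosome 6 at 57483983 to 57486006 and on chromosome 4 at 82150557 to 82153113 and 82156398 to 82157931 in replicate 1, chosen after their values were seen. The order among scores at or above 3100 is not read as strength, and pairs at exactly 3100 need not be weaker than those above it. With those scores taken as equal, 53 pairs tied for the best rank, and the pair on chromosome 3 at 62941267 to 62942250, which was below the ceiling in replicate 2, came after them.

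NR6A1 peaks were unevenly spread over the chromosomes, in a like order in both replicates. Chromosome 19 was the densest, with 13.5 peaks per Mb in replicate 1 and 9.85 in replicate 2. Chromosome 10 followed in replicate 1 with 12.8 peaks per Mb and had 8.41 in replicate 2, and chromosome 15 had 11.3 and 9.31. The sparsest autosome was chromosome 12, with 4.73 and 3.21 peaks per Mb. Chromosome X had 261 peaks in replicate 1 and 266 in replicate 2, or 1.57 and 1.60 per Mb. The autosomes together were 5.48-fold denser than X in replicate 1 and 4.03-fold denser in replicate 2. The list held no peak on chromosome Y or on the mitochondrial genome in either replicate, and 11 and 6 peaks lay on unplaced contigs. Over the 19 autosomes the densities of the replicates had a Pearson r of 0.92 and a Spearman rho of 0.90 (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations allow, and 3e-05 after Benjamini-Hochberg adjustment over 3 relations). Without the 2 chromosomes farthest from the median, r was 0.90. Chromosomes of 1 cell line are not independent samples. No vector list was set beside these densities or the window counts below, so a likeness common to any library of these cells cannot be told apart. Chromosome X was the one chromosome with fewer peaks in replicate 1 than in replicate 2, at a ratio of 0.98, while the autosomes ranged from 1.08 on chromosome 4 to 1.75 on chromosome 14.

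**Figure D3:**
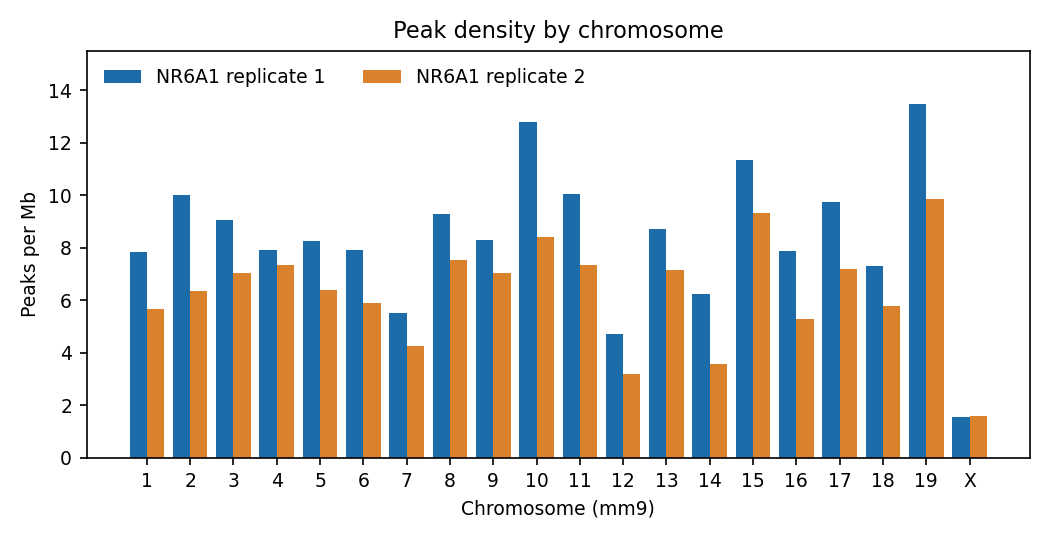
Peaks per Mb of mm9 sequence (y axis) on each autosome and on chromosome X (x axis) for NR6A1 replicates 1 and 2, with 1 peak list behind each bar and so no error bar. Chromosome 19 is highest at 13.5 and 9.85 peaks per Mb, and X is lowest at 1.57 and 1.60.

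Peaks also gathered within chromosomes. In replicate 1, 47.2% of peaks had another peak of the same list within 10 kb (46.5 to 47.8%), against 16.3 ± 0.34% in 1000 shuffles (SD), a 2.89-fold excess. In replicate 2 it was 42.9% (42.1 to 43.6%) against 12.5 ± 0.35%, a 3.43-fold excess. Regions found in both lists gathered likewise, 31.0% (30.0 to 31.9%) against 7.32 ± 0.39%, a 4.23-fold excess. One-sided permutation p was 0.001 for each, the smallest the shuffles allow. These shuffles also reach unsequenced or unmappable stretches, which can enlarge the excess, and no shuffle within 50 to 100 kb was made for this measure. Counts per 1-Mb window had a rho of 0.89 between the replicates over 2649 windows. In 18 windows the count exceeded that of every window in every shuffle in both replicates. The densest was 5 to 6 Mb on chromosome 19, with 48 peaks in replicate 1 and 45 in replicate 2, of which 31 regions were in both. By the sum of both replicates it was followed by 129 to 130 Mb on chromosome 8, with 43 and 41 peaks, and by 125 to 126 Mb on chromosome 2, with 46 and 34. At the other end, 530 windows held no peak in either replicate. Replicate 1 alone left 666 windows empty, against 38.7 in shuffles, which do not avoid unsequenced stretches.

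Regions in both lists that followed each other with gaps of at most 10 kb formed 292 clusters of 3 or more, which held 993 regions or 11.0% of the regions in both. The cluster with the most regions was on chromosome 6 at 52154124 to 52210125, where 12 regions in both lists lay within 56.0 kb. It had 15 peaks in replicate 1, with a highest score of 2834.45, and 16 in replicate 2, with a highest score of 2813.72. A cluster of 8 regions lay on chromosome 10 at 79603880 to 79629016, and one of 7 on chromosome 11 at 8574645 to 8605766. Clusters of 6 regions included those on chromosome 17 at 29183882 to 29201307, with highest scores of 3100 and 1152.79, on chromosome 8 at 129350016 to 129377454, with 2164.2 and 3100, and on chromosome 5 at 31904672 to 31933001, with 1847.3 and 3100. The genes at these positions were not analysed here.

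**Figure D4:**
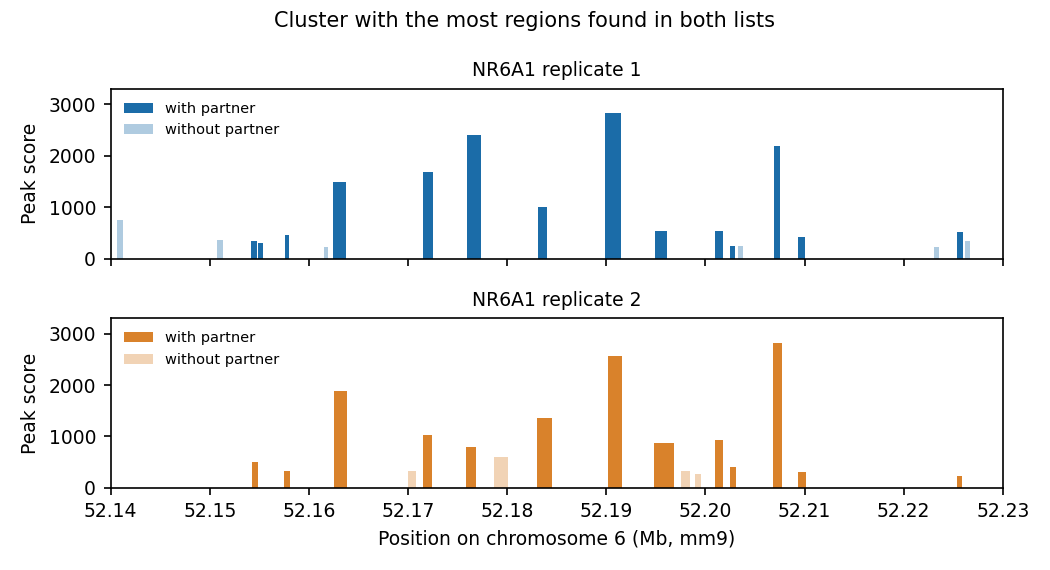
Peaks on chromosome 6 around the cluster with the most regions found in both lists, drawn to scale by position (x axis, Mb, mm9) with the authors' peak score as height (y axis), for NR6A1 replicate 1 (top) and replicate 2 (bottom), and paler where a peak has no partner in the other list. Both replicates have a row of separate peaks here, with highest scores of 2834.45 and 2813.72 at different peaks.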

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

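The other shuffles, the removal of peaks at or above 3100, the restriction to autosomes and the neighbour distances of 5 and 50 kb were chosen after seeing the data. The excess of partner peaks over shuffles kept its direction and its side of the threshold in all 9 alternatives for both replicates, but its size changed with the setting: for replicate 1 peaks it was 125-fold with a 50% reciprocal overlap, 260-fold with midpoints within 100 bp, 75.1-fold in the upper 50% and 23.8-fold with shuffles by 50 to 100 kb, against 50.3-fold as reported. The excess of close neighbours kept its direction and side at 5 and 50 kb, which are 2 alternatives. The size of that excess fell with distance, from 3.84-fold at 5 kb to 1.43-fold at 50 kb in replicate 1, from 4.62-fold to 1.58-fold in replicate 2 and from 5.36-fold to 2.05-fold for regions in both lists. Of 69 values under an alternative, 50 stayed within the limit set for them and 19 moved, and none reversed. The 2 other kinds of shuffle change only the random placements, so their counts, shares and rho stayed by construction and are among the 50. A count alone cannot reverse. Taking only the upper 50% of each list by score left 4091 replicate 1 and 4056 replicate 2 peaks with a partner. Their shares of the kept peaks were 38.0% and 50.2%, against 42.7% and 56.0% as reported. That setting shortens each list and by construction also drops partners in the lower 50% of the other list. The rho of partner scores was 0.44 with a 50% reciprocal overlap and 0.44 with midpoints within 100 bp, 0.34 in the upper 50%, 0.36 with equal list sizes and 0.34 without peaks at or above 3100. The share of the highest decile of replicate 1 without a partner, 34.8% as reported, was 38.3% with reciprocal overlap, 50.3% with close midpoints, 39.1% in the upper 50%, 32.2% with equal list sizes, 38.6% without the widest peaks and 41.1% without peaks at or above 3100. For replicate 2, at 9.96% as reported, the same settings gave 19.5%, 30.7%, 15.3%, 13.6%, 13.1% and 16.0%. The share stayed higher in replicate 1 under each of these settings. The cause of these moves was not tested beyond the construction of each setting. No paired analysis was possible because no peak list was used for the vector libraries, so the shared replicate numbers could not be used. Leaving out a replicate leaves no partner to count, and the results and alternatives on promoters, gene lists, the motif and the Nr6a1 locus were not run for want of an mm9 annotation and sequence. The lists give no reads per peak, so a peak missing from one list cannot be told from one just under its threshold.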

Other observations

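The tests in this part were chosen after the lists had been seen. That of the runs was set before the runs were counted, but after the correlation between neighbouring peaks given below was known. The tests of whole chromosomes and of long segments took the place of an earlier test of segments, that same correlation beyond 50 kb, after its value had been seen. The test of depth and sensitivity took the place of one on the share of strong peaks without a partner, which is part of the pattern itself.

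Regions found in replicate 1 only lay in stretches. The longest run of consecutive regions with no replicate 2 peak among them held 27 regions on chromosome 10 at 83111259 to 83724382, over 613 kb. Another held 26 on chromosome 10 at 103079146 to 106491675, with a peak at the score ceiling. A compact run of 16 regions lay on chromosome 15 at 6969590 to 7086557, within 117 kb and also with a peak at the ceiling. The longest runs of replicate 2 only held 11 regions, on chromosome 7 at 111681650 to 112607495 and on chromosome 8 at 14331180 to 14717561. A hypothesis of independent loss of single peaks was tested by permuting the list labels 1000 times within chromosome and score quintile. There were 122 runs of 8 or more replicate-1-only regions, against 24.0 ± 4.68 (SD) and at most 39 in the permutations (p = 0.001, the smallest they allow), which argues against it. For replicate 2 there were 12 such runs, against 0.587 and at most 4. The longest run in any permutation held 19 regions for replicate 1, below the 27 observed, and 16 for replicate 2, above the 11 observed. Run lengths are not compared between the replicates, since 12317 regions were in replicate 1 only and 7118 in replicate 2 only.

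The strongest replicate 1 peaks without a partner are the pattern that would most repay another look. At a score of 3000 or more, 26.8% of replicate 1 peaks had none, against 3.96% of replicate 2 peaks. A common loss of depth or sensitivity in replicate 2 was considered first. With no scatter, it would have to lower scores about 5-fold to take 1000 to the minimum near 200, a log2 ratio of 2.32. Partner pairs with a geometric mean score of 1000 or more and both scores below the ceiling were taken, where the minimum can remove no pair. Over these 1393 pairs the median log2 ratio of replicate 1 over replicate 2 was -0.0099 (bootstrap 95% interval -0.08 to 0.05). This argues against a common loss of that size for strong peaks found in both lists. Together the limits leave out pairs with the largest ratios, which draws the median toward equality, and peaks without a partner do not enter it. A smaller common loss acting with the scatter of scores (SD of log2 ratio 1.11 over all partner pairs) was not tested. A loss for weak peaks was not tested. Shifted boundaries are also argued against, since 4.49% of the partnerless peaks at 1000 or more had a replicate 2 peak within 1 kb. A gain or loss of whole chromosomes is argued against as the only cause. Even on chromosome 15, where the share was lowest, 32.5% of strong replicate 1 peaks lacked a partner. The share was highest on X, at 45.8%, and changes of some chromosomes cannot be excluded for a part of these peaks. Loss of segments that hold 8 or more regions from the replicate 2 culture would place the peaks of those segments in runs of 8 or more. Of the partnerless peaks at 1000 or more, 14.3% lay in such runs, so loss of such segments may account for a part at most. Loss of shorter segments cannot be judged this way, since the median 1-Mb window held 6 replicate 1 peaks and a single replicate 2 peak ends a run. Scatter of scores between the lists stays open for a part of these peaks. For replicate 1 peaks at 1000 to 2000, the 5th percentile of partner scores was 241, near the minimum, and at 3000 or more it was 303. For replicate 2 peaks of the same classes it was 258 and 420. At 1000 to 2000 the percentiles of the replicates were thus close, yet the shares without a partner differed. There, 1041 of 2542 replicate 1 peaks had none, against 249 of 1632 in replicate 2. Partner scores near the minimum therefore do not by themselves account for the difference between the replicates. Also open is a difference shared by neighbouring peaks, such as chromatin state, the control library used in peak calling or other material in a library. Among replicate 1 peaks at 1000 or more, the presence of a partner had a correlation of 0.40 over 180 pairs of neighbours under 5 kb apart. It was 0.156 at 5 to 50 kb over 673 pairs and 0.065 at 50 to 500 kb over 1471 (permutation p = 0.001, 0.001 and 0.004). In replicate 2 the same correlations were 0.28, -0.046 and 0.051, over only 89, 329 and 797 pairs (permutation p = 0.02, 0.9 and 0.1). Over peaks of all scores they were 0.25, 0.098 and 0.054 in replicate 1 and 0.14, 0.058 and 0.061 in replicate 2. Permutation p was 0.001 for each of these. With all peaks taken, neighbours were thus alike in presence in both replicates. No biological explanation was tested, since the design places both replicates in 1 group.

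A second pattern is the spread of peak density over autosomes. A candidate explanation is a difference in chromosome copy number in the clonal line, which would raise density and scores together. Over the 19 autosomes, density and median score had a Spearman rho of 0.24 in replicate 1 (two-sided permutation p = 0.31, adjusted 0.31) and 0.38 in replicate 2 (p = 0.11, adjusted 0.16), and a Pearson r of 0.50 (p = 0.029, adjusted 0.044) and 0.39 (p = 0.1, adjusted 0.1). Without the 2 chromosomes farthest from the median density, rho was 0.19 in replicate 1 and 0.48 in replicate 2, and r was 0.49 and 0.48. Copy number cannot be told apart here from the gene content or mappability of each chromosome, because no coverage of unenriched DNA was used. The low density on X has the same open explanations.

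Individual sites illustrate the difference between the replicates. In replicate 1, peaks with no partner included chromosome 8 at 64275825 to 64276795 (score 3199.4) and chromosome 10 at 109475466 to 109476354 (score 3178.11). The nearest replicate 2 peak to the first of these was 39.3 kb away. In replicate 2, the peak with no partner and the highest score was on chromosome 15 at 103258598 to 103259580 (score 3166.84), 63.8 kb from the nearest replicate 1 peak.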
